A study of Daphnia magna with 12 samples.

How the data were processed

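Total RNA of 12 pools, each of 40 Daphnia magna exposed for 96 hours with the medium renewed after 48 hours, was labelled from 100 ng with the Agilent Low Input Quick Amp kit, per the labels' protocols. Each array held 1 pool and the common copper reference, in opposite dyes. The deposited file was the value table of the series, with 1 column per array and 4262 rows. The authors deposited its values as log ratios of the 2 channels, and they were read as log2 because limma, named in the submitters' processing notes without a version, works on that scale. Background correction, normalization within and between arrays, the array software and the rule that chose the rows are not given in the sources used here. Probe numbers run up to 15415, so the 4247 probes analysed may be only part of the array, and every count holds for these rows only. Of these rows 53.9% had an unadjusted p of 0.05 or more in the F test over the 3 groups. The rows were thus not chosen by that test at that threshold, but other ways of choosing responding probes are not excluded. The scanner signals, dim-probe flags and slides were not used here, and zinc exposures named in the design text were not analysed here. Every column of the table belongs to a sample of the series.

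Scale, centring and direction of the table are not stated, so they were checked before any call was counted. Column medians lay between -0.06 (CuCl2 replicate 4) and 0.04 (CuO replicate 1): CuO replicates 2, 3 and 4 had -0.005, -0.011 and -0.009, CuCl2 replicates 1, 2 and 3 had 0.003, 0.006 and -0.022, and blank replicates 1 to 4 had -0.026, -0.017, -0.019 and -0.053. All 15 control probes had opposite mean signs on the cy3 and cy5 arrays (r = -0.996 across controls), while the centred group means of the other probes correlated positively between orientations (r = 0.75). The columns were therefore taken as already turned one way and were not turned again. The sign of the whole table was taken from the reference, which is an equal mixture of the 3 groups, so that the linear ratios of the group means should average 1 for a probe, a log2 of 0. For the 92 probes whose group means spanned at least 2 on the log2 scale, the median of that log2 average was -0.08 as deposited and 0.88 with the sign turned. Sample over reference is thus the likely direction, on the basis of the design and not of a statement by the authors. The same value was 0.04 if the table were on a natural log scale and 0.77 for log10, so this check argues against log10 but does not separate base 2 from the natural log, on which every fold would be larger. Arrays of one orientation correlated down to r = -0.55 (blank replicate 3 and CuCl2 replicate 4). The labels state the dyes, and blank and copper samples can lie on opposite sides of a reference mixed from both, so the direction was kept.

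The groups were compared with limma 3.58.1 in R 4.3.3 by fitting group and dye orientation on all 12 arrays (8 residual degrees of freedom), with an empirical Bayes prior and Benjamini-Hochberg adjustment over the 4247 probes at 0.05. The dye term itself passed this threshold for 1388 probes. Fold changes are differences of group means of log2 ratios, so the reference cancels. Group means and SDs of single probes are given after centring each dye orientation. The labels describe separate replicate exposures. No 2 replicates of a group held the same values, and replicates of a group differed by root mean squares of 0.35 to 0.72. The replicate numbers were not used to pair samples.

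The rule for named probes, fixed before the data were examined, took for each comparison the 2 largest rises and 2 largest falls among called probes whose groups did not overlap, or the smallest p-values where none passed. The files pair no probe with a gene, and 0 of the 4247 IDs occur in the Daphnia magna RefSeq gene table (assembly ASM2063170v1.1). Gene lists fixed by name could therefore not be tested. The fit was tested on simulated data with 200 changed probes among 4247 over 20 runs. For CuO against blank it recovered 44.1% of 1.5-fold, 84.1% of 2-fold and 97.8% of 4-fold changes, with 4.6% false calls. For CuCl2 against blank the same shares were 45.4%, 81.8% and 97.8%. Alternatives were the dye term, the replicate block, centring, quantile normalization and scaling of arrays, the groups in the fit, the prior, array weights, a 1.5-fold minimum, the more variable probes, and leaving out each array. The response score, the contrast of both copper groups against blank and the F test over the 3 groups were added after the data were seen. So were the counts of calls within one dye orientation and the noise-corrected correlation from sets of arrays that share no array. The omission of CuCl2 replicates 2 and 4 was added then as well.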

Results

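Gene expression was measured in whole water fleas (Daphnia magna, a small freshwater crustacean used in toxicity testing) after 96 hours in 1 of 3 media. These held copper oxide (CuO) nanoparticles, the dissolved copper salt CuCl2, or no added copper (blank). Both copper forms were given at the concentration labelled as EC10 for immobilisation, the level at which a small share of animals stops moving, so the doses were matched by effect and not by copper mass. Each group had 4 replicates, each an RNA pool of 40 daphnids, and each pool was hybridised on 1 two-colour Agilent array against a common copper reference mixed from equal parts of the 3 groups. In every group 2 pools carried the dye cy3 and 2 carried cy5. The value table held 4247 probes after 15 control probes were set aside, with 0 missing values. The files and the gene table used here do not pair these probes with genes, so results are given for the probes as a population and for a few probes by ID. The number of arrays limits the precision, and signal intensities were not used here.

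The signs below rest on reading the table as sample over reference, which its authors do not state, and the sizes rest on an assumed log base of 2. An equal mixture of the groups requires linear ratios that average 1 over the groups, and the table met this within a median of 0.08 on the log2 scale for the probes of widest range.

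**Figure D1:**
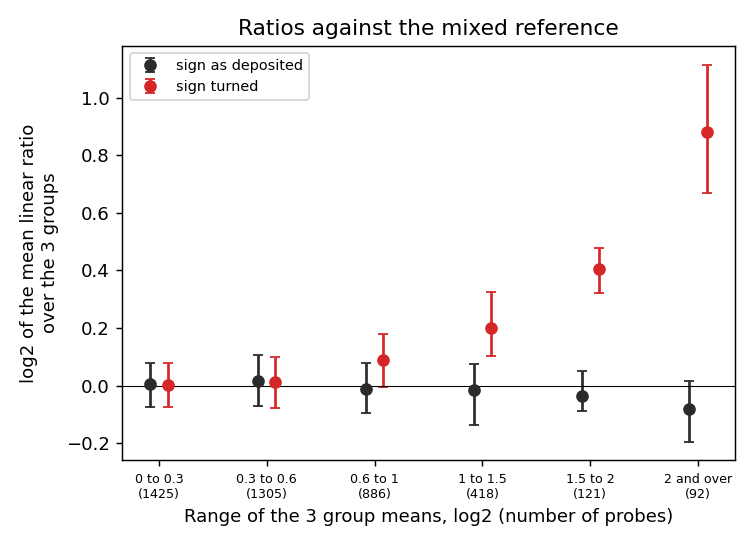
Log2 of the mean linear ratio to the mixed reference over the 3 groups (vertical axis), for probes binned by the range of their 3 group means (horizontal axis, log2, with the number of probes). Points are medians with bars from the lower to the upper quartile, and for the 92 probes of widest range the median is -0.08 as deposited and 0.88 with the sign turned.

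Copper exposure separated the animals from the blanks along the main axis of variation. The first principal component of the dye-centred log2 ratios held 57.9% of the variance. All 4 blanks lay between 0.31 and 0.44 on it, and all 8 copper arrays lay between -0.44 and -0.03. The second component did not follow the exposure, since CuCl2 replicates 1 and 4 and blank replicates 1, 2 and 4 were positive on it and the other arrays negative. Log2 ratios spread more widely on the blank arrays (SD over probes 0.605 ± 0.051, mean ± SD, n = 4) than on the CuO arrays (0.415 ± 0.039, n = 4). The CuCl2 arrays had 0.484 ± 0.153 (n = 4). The reference was itself mixed in equal parts from both copper groups, whose effects were alike (below), and the blank, so it lies nearer to the copper samples. The mixture alone thus gives the blank arrays wider ratios, and this spread does not measure variation between blank animals.

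The first comparison asked which transcripts respond to CuO nanoparticles. Of the 4247 probes, 1279 (30.1%) changed against blank, 741 higher and 538 lower (limma moderated test, two-sided, Benjamini-Hochberg adjusted p under 0.05). The median size of a called change was 0.70 on the log2 scale. At least a 2-fold change was seen for 239 of the higher and 81 of the lower probes, and the 4-fold level was passed by 46 and 6. Called rises over 4-fold numbered 19 after quantile normalization and 30 with the arrays scaled to one median absolute deviation, and without blank replicate 4 the called falls of at least 2-fold numbered 45. The largest rise was that of probe DM11354P1, whose log2 ratio to the reference was -3.64 ± 0.22 in blank animals and 0.49 ± 0.46 in CuO animals (mean ± SD, n = 4 each). This was a 17.6-fold rise (log2 fold change 4.14, SE 0.28, limma adjusted p = 1.43e-05). DM09121P1 rose 12.5-fold (log2 fold change 3.65, SE 0.34, limma adjusted p = 6.67e-05), with a log2 fold change of 3.01 after quantile normalization. Among the lower probes, DM07144P1 fell by 2.44 on the log2 scale (SE 0.26, limma adjusted p = 0.000182). DM00920P3 fell by 2.49 (SE 0.68, limma adjusted p = 0.0193), but its 4 CuO values ranged from -4.11 to -0.88, and its call was lost without blank replicate 3 (limma adjusted p = 0.0524) or blank replicate 4 (limma adjusted p = 0.0623). Its log2 fold change was -1.73 without CuO replicate 3, -0.77 on the cy3 arrays alone and -4.22 on the cy5 arrays alone. Over the 23 alternative settings run for it, its limma adjusted p ran from 0.0104 to 0.389. Its group means were -2.08 ± 1.44 in CuO, -0.09 ± 0.75 in CuCl2 and 0.41 ± 0.84 in blank animals (mean ± SD, n = 4 each). Neither its CuCl2 effect of -0.50 (limma adjusted p = 0.578) nor its difference between the copper forms (limma adjusted p = 0.839) passed. In 1162 of the called probes the 4 CuO values all lay on one side of the 4 blank values. Such separation occurred for 35.2% of all probes. For exchangeable values chance gives 2.86%, but values centred within each dye orientation are not strictly exchangeable. Between CuO and CuCl2 arrays separation occurred for 3.58% of all probes.

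The count for CuO was 629 with no dye term in the fit and 847 with a change of at least 1.5-fold required as well. Of the arrays left out in turn, CuO replicate 1 and blank replicate 4 moved it most, to 806 and 827. Within one dye orientation, with 2 arrays per group, 46 probes passed on the cy3 arrays and 272 on the cy5 arrays. Quantile normalization between arrays gave 1133 calls, of which 47.8% were higher, against 57.9% in the table as deposited. The share was 51.7% with each array centred on its median and 57.1% with the arrays scaled to one median absolute deviation. The balance of rises and falls thus depended on centring and quantile normalization, and little on that scaling.

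**Figure D2:**
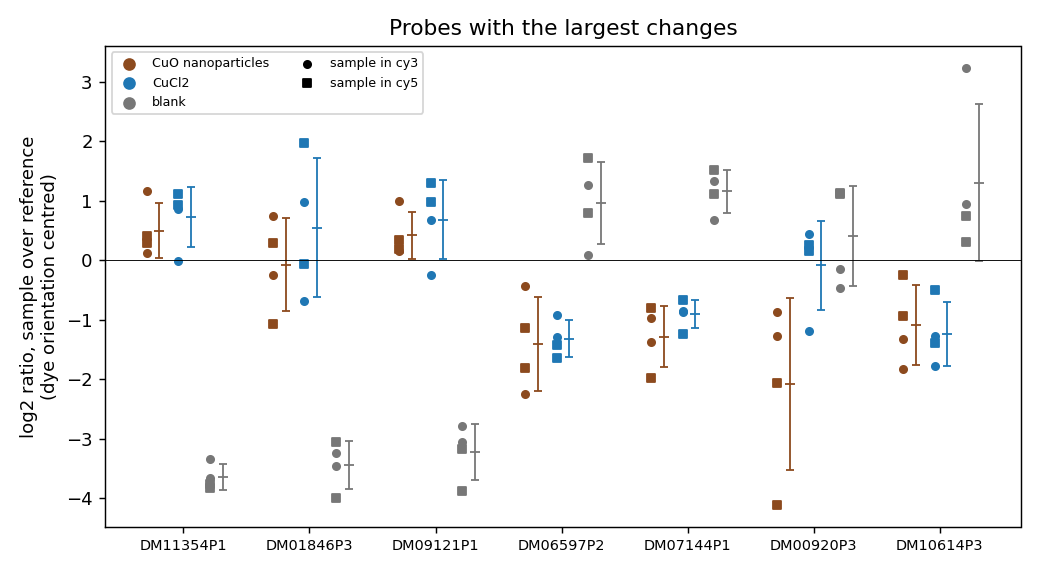
Log2 ratio of sample over reference (vertical axis, centred per dye orientation) for the 7 probes (horizontal axis) that give the 2 largest called rises and 2 largest called falls of either copper group against blank, among probes whose groups did not overlap. Points are arrays, circles with the sample in cy3 and squares in cy5, bars give the mean ± SD of 4 arrays, and the blanks of DM11354P1 average -3.64, below every copper array.

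The second comparison asked the same of the dissolved salt. CuCl2 changed 1726 of the 4247 probes (40.6%) against blank, 898 higher and 828 lower (limma, adjusted p under 0.05), with a median called change of 0.75 on the log2 scale. At least a 2-fold change was seen for 320 of the higher and 204 of the lower probes, and the 4-fold level was passed by 84 and 5. After quantile normalization 191 called rises were at least 2-fold and 28 over 4-fold, and with the arrays scaled to one median absolute deviation 134 called falls were at least 2-fold and 49 called rises over 4-fold. Called rises over 4-fold numbered 55 without CuCl2 replicate 4. Called falls over 4-fold numbered 2 without blank replicate 4, 10 without CuCl2 replicate 2, and 8 without CuCl2 replicate 1, CuCl2 replicate 3 or blank replicate 1. DM11354P1 again rose most, 20.7-fold (log2 fold change 4.37, SE 0.28, limma adjusted p = 5.99e-06), with a log2 fold change of 3.76 with the arrays scaled to one median absolute deviation. DM01846P3 rose 15.8-fold (log2 fold change 3.98, SE 0.54, limma adjusted p = 0.000361), with a log2 fold change of 3.12 after quantile normalization and 3.35 with that scaling, and the call was lost on the cy3 arrays alone (log2 fold change 3.49). In CuO animals it rose 10.3-fold (limma adjusted p = 0.00154), with a log2 fold change of 2.67 after quantile normalization. That CuO call was lost within either dye orientation alone, and its limma adjusted p over the 23 settings ran from 0.000203 to 0.0813. DM10614P3 fell by 2.54 on the log2 scale (SE 0.58, limma adjusted p = 0.00643) and DM06597P2 fell by 2.28 (SE 0.41, limma adjusted p = 0.00193). The size of the fall of DM10614P3 depended on blank replicate 2, whose dye-centred log2 ratio was 3.23 against 0.30 to 0.94 in the other blanks. Without it the CuCl2 log2 fold change was -1.82, and it was -3.62 on the cy3 arrays alone, where the call was lost, and -1.47 on the cy5 arrays alone. Over the 23 settings its limma adjusted p in CuCl2 animals ran from 0.00192 to 0.0715. In CuO animals DM06597P2 fell by 2.37. On the cy3 arrays alone DM06597P2 lost its call in both copper groups, with log2 fold changes of -1.78 in CuCl2 and -2.02 in CuO animals. DM10614P3 fell by 2.39 in CuO animals, or by 1.66 without blank replicate 2. That call was lost with no dye term and within either dye orientation, where the log2 fold change was -3.66 on the cy3 arrays and -1.11 on the cy5 arrays, and its limma adjusted p over the 23 settings ran from 0.00243 to 0.134. Quantile normalization gave 1329 calls for CuCl2, of which 47.8% were higher, against 52.0% as deposited, so the majority turned with this normalization. The share was 50.7% with each array centred on its median and 53.1% with the arrays scaled to one median absolute deviation. The count was 1058 with no dye term. Within one dye orientation the count for CuCl2 was 39 on the cy3 arrays and 1143 on the cy5 arrays.

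The 2 lists of called probes overlapped widely. Of the 741 probes higher in CuO, 639 were also called higher in CuCl2, and 487 of the 538 lower probes were also called lower. Independent lists of these sizes would share 157 and 105. None of the 1126 probes called in both comparisons moved in opposite directions. Over all probes the CuO and CuCl2 effects correlated with Pearson r = 0.93 and Spearman rho = 0.92, across probes, which are not independent replicates. Both comparisons used the same blanks, and unchanged groups simulated against shared blanks gave a mean r of 0.50 (100 draws) and 0.03 probes called in both. With no probe changed, the adjusted threshold leaves few calls in either comparison. That count therefore cannot show how many of the shared calls come from the common blanks. The covariance of the effects was 0.409, against 0.0250 in the simulation, a difference of 0.384. With the blanks split so that each effect used other blank arrays, r lay between 0.74 and 0.89. A noise-corrected estimate, built from covariances between sets of arrays that had no array in common, was 0.99 and 0.98 for the 2 splits. It is a ratio of covariances and not an observed correlation. The same covariances gave a ratio of the CuO to the CuCl2 effect SD of 0.81 and 0.84. Both splits reuse the same arrays, so their closeness is not replication, and no error of this ratio was computed. It includes CuCl2 replicate 4, whose log2 ratios had an SD of 0.711, against 0.386 to 0.434 on the other CuCl2 arrays. The ratio was not recomputed without that array, so it does not establish weaker CuO effects. Within one dye orientation r was 0.91 on the cy3 arrays and 0.89 on the cy5 arrays.

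**Figure D3:**
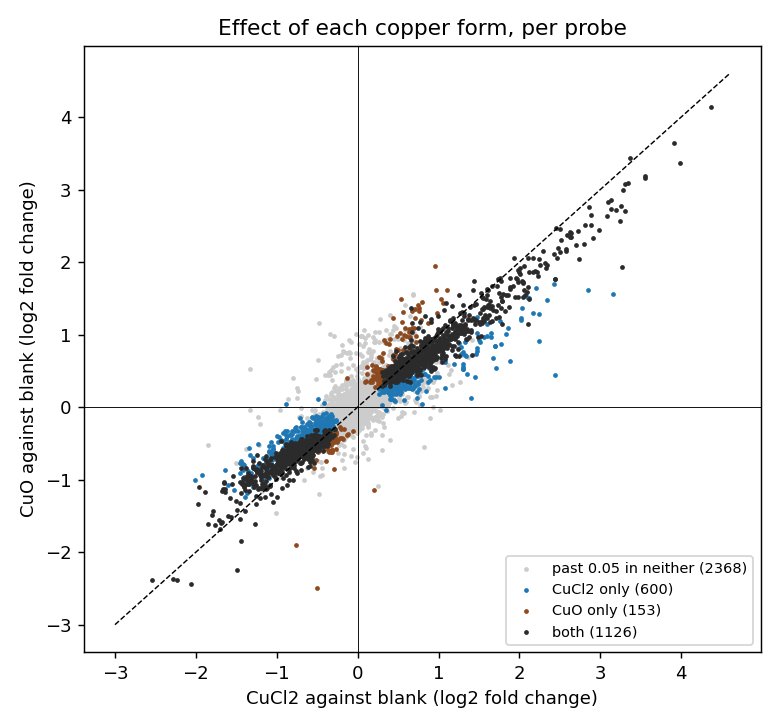
Log2 fold change against blank of each of 4247 probes in CuO nanoparticle animals (vertical axis) and CuCl2 animals (horizontal axis), with colours for the comparisons in which the probe passed an adjusted p of 0.05. The dashed line marks equal effects, both axes share the same 4 blank arrays, and the 1126 probes called in both lie at the upper right and lower left.

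The third comparison set the nanoparticle directly against the dissolved salt. Of the 4247 probes 0 differed between CuO and CuCl2 animals (limma, adjusted p under 0.05), and the smallest adjusted p was 0.839. At an unadjusted p under 0.05 there were 198 probes (4.66%). The smallest p-values in each direction belonged to 4 probes that did not pass. Their 95% intervals are for each probe alone, with no allowance for choosing the smallest p-values among 4247. That these intervals exclude 0 is thus no evidence of a difference, and the estimates are likely too large. Among those higher in CuO, DM06499P3 had a log2 difference of 0.93 (95% interval 0.42 to 1.43) and DM06484P3 one of 0.52 (0.23 to 0.82). Among those lower in CuO, DM02083P4 had a log2 difference of -0.50 (-0.76 to -0.25) and DM08407P1 one of -1.25 (-1.89 to -0.61). DM08407P1 rose against blank in CuCl2 animals (log2 fold change 1.88, limma adjusted p = 0.000784), and in CuO animals its log2 fold change was 0.63 (limma adjusted p = 0.118). Its CuO log2 fold change depended on the dye orientation, with 1.08 on the cy3 arrays alone and 0.18 on the cy5 arrays alone. The difference between the forms was -0.71 on the cy3 arrays and -1.78 on the cy5 arrays. The most changed probe, DM11354P1, differed between the forms by -0.23 (SE 0.28).

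The precision of the direct comparison bounded the difference within 2-fold for most probes but not all. The 95% interval of the difference lay within 2-fold either way for 88.2% of the probes and within 1.5-fold for 63.2%. For the 1879 probes changed against blank in either copper group, the shares were 88.0% and 55.3%. A 2-fold bound is wider than the median called change against blank, which was 0.70 for CuO and 0.75 for CuCl2 on the log2 scale. An interval within 2-fold can thus still hold a difference as large as a typical called effect. On simulated data of the same size, with differences between CuO and CuCl2 of known fold, 84.8% of 2-fold and 43.1% of 1.5-fold differences were called. Those data had 200 changed probes and, for each probe, the same spread on every array. With fewer changed probes the adjusted threshold is harder to pass, so these shares need not hold for a few differing probes. The cy3 arrays alone gave 0 probes and the cy5 arrays alone gave 1.

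A response score placed each array on the copper-against-blank axis computed from the arrays of the other dye orientation. The blanks of its own orientation average 0, and the mean copper effect of the other orientation is 1. CuO arrays scored 0.784 ± 0.155 and CuCl2 arrays 0.919 ± 0.299 (mean ± SD, n = 4 each). The copper arrays ran from 0.517 to 0.912 on cy3 and from 0.797 to 1.23 on cy5, so the SDs include a difference between the dye orientations. The blanks lay within 0.095 of 0. The 2 blanks of an orientation are centred on their own mean, so this understates their scatter. The difference between the copper forms was -0.135 (two-sided exact permutation test within dye orientation, p = 0.389). The 36 regroupings of this design cannot give a p below 0.0556. With the score of CuCl2 replicate 4 left out of its group mean the difference was -0.03, and with that of CuCl2 replicate 2 left out it was -0.27. The axes were not recomputed, so the array left out still helped to set the axis for the other dye orientation. Leaving out 1 array also unbalances the dye orientations, so these shifts include the offset between them.

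**Figure D4:**
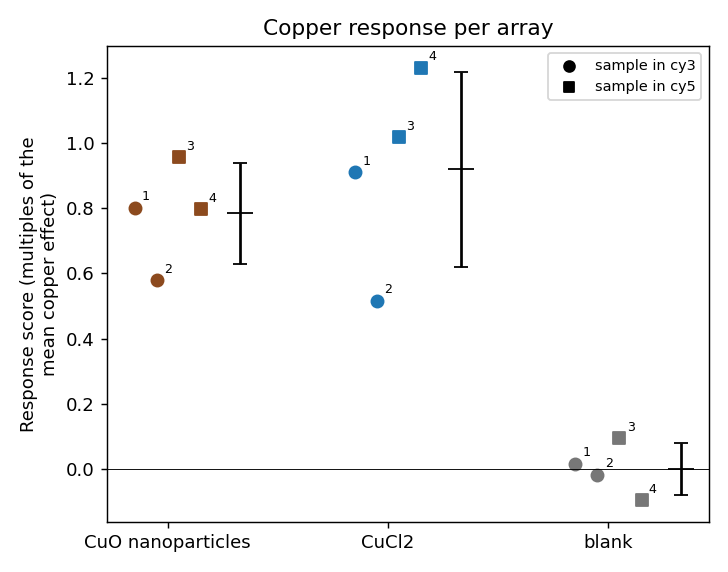
Response score of each array (vertical axis, in multiples of the mean copper effect in the other dye orientation) by exposure group. Labels give the replicate number, with circles for samples in cy3 and squares for samples in cy5. Bars give the mean ± SD of 4 arrays over both dye orientations, and all 8 copper arrays lie between 0.517 and 1.23, above the 4 blanks.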

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

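The correlations that centring alone gives and the dye effects from separate arrays were computed after the other results were seen. Of 41 sets of 4 values checked for a single distant array, 2 stood out, and chance gives about 1 in 20. The SD of log2 ratios over probes was 0.711 on CuCl2 replicate 4, against 0.386 to 0.434 on the other CuCl2 arrays. It was 0.357 on CuO replicate 4, against 0.429 to 0.439 on the other CuO arrays.

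Deviations of CuCl2 replicate 4 from its group opposed those of replicates 2 and 3 over probes (r = -0.76 and -0.69) and not those of replicate 1 (r = 0.24), where centring alone gives independent arrays of these spreads -0.46, -0.63 and -0.28. Array scale stays open: with every array scaled to one median absolute deviation, r of replicates 2 and 4 was -0.65 against -0.42 from centring alone, and the bound set beforehand had assumed arrays of equal spread. Dye bias also stays open: the difference of the 2 arrays, less the dye effect of the other 8 arrays, had r = -0.0130 with that dye effect, but 0.003 and 0.154 where the effect removed and the effect compared came from separate arrays. Unequal strength of the copper response may account for part of it, since the same difference had r = 0.41 with the CuO effect, which uses neither array, and this lies between the 0.3 and 0.5 set as bounds and decides nothing. A difference between the exposed pools themselves stays open and untested.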

How the results depend on the processing

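The counts within one dye orientation and the noise-corrected correlation between sets that share no array were chosen after the data were seen. So was the fit without CuCl2 replicates 2 and 4. The direction of each named probe, in the comparison that named it, held under every alternative run for it. Without the dye term the counts were 629 for CuO and 1058 for CuCl2 against blank, all among the probes called with it, and dye differences then remained in the residual spread. A minimum of 1.5-fold left 847 for CuO. Leaving out 1 array gave 806 to 1378 for CuO, lowest without CuO replicate 1 and next (827) without blank replicate 4, and 1315 to 1896 for CuCl2. Within one dye orientation, with 2 arrays per group, CuO gave 46 (cy3) and 272 (cy5), CuCl2 39 and 1143, and CuO against CuCl2 0 and 1. Every other setting tried moved the counts against blank by less than 1.5 times and left CuO against CuCl2 at 0. With the replicate block, CuO gave 1232, CuCl2 1693 and CuO against CuCl2 0 calls. The replicate numbers gave no clear sign of pairing: 4 of the 12 same-numbered pairs had deviations correlating above 0.1 (range -0.36 to 0.32). Of the 12 arrays, 1 correlated best with its own number. Same-numbered arrays always share a dye orientation, and centring by orientation lowers their correlation, so this check cannot exclude pairing. With the blanks split, the correlation of the effects was 0.828, 0.780, 0.737 and 0.893, with more noise from fewer blanks. The noise-corrected estimate, from covariances between sets that share no array, was 0.986 and 0.984 and is not an observed correlation. Leaving out both CuCl2 arrays 2 and 4 gave 1430, 1440 and 0 calls. DM00920P3 lost its call on the cy3 arrays and without blank replicate 3 or 4. DM01846P3, DM10614P3 and DM06597P2 lost their CuCl2 and CuO calls on the cy3 arrays, DM01846P3 and DM10614P3 also their CuO calls on the cy5 arrays, and DM10614P3 its CuO call with no dye term. The gene list tests and the averaging of probes per gene were not run, because no probe has a gene name, and a filter on missing values would remove no probe. Signal over background was not used here, so limits from dim probes are unknown.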

Other observations

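The contrast of both copper groups with blank, its tests and the count of splits that keep the dyes balanced were chosen after the data were seen. So were the counts over 4-fold after quantile normalization and scaling.

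Between blank and the mean of both copper groups, 1907 of the 4247 probes differed (1001 higher and 906 lower in copper, limma adjusted p under 0.05), and 60 rose and 4 fell over 4-fold. After quantile normalization 46.5% of the calls were higher, against 52.5% as deposited. The share was 49.6% with each array centred on its median and 52.9% with the arrays scaled to one median absolute deviation. With no dye term 1243 probes differed. In 58 of the 60 the CuO effect was smaller than the CuCl2 effect, with medians of 2.34 and 2.67 on the log2 scale. The mean over these probes differed by -0.39 between CuO and CuCl2 arrays (n = 4 each, two-sided exact permutation test within dye orientation, p = 0.333, smallest possible 0.0556). Without CuCl2 replicate 4 the count was 45 of 60 and the median difference went from -0.33 to -0.12, and without CuCl2 replicate 2 they were 60 of 60 and -0.56. After quantile normalization they were 52 of 60 and -0.16. The count was 33 of 60 on the cy3 arrays and 60 of 60 on the cy5 arrays.

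Chance assignment of arrays was tested by regrouping. Of the 35 splits of the CuO and blank arrays into 4 and 4, only 1, the real one with 1279 calls, gave as many, and the highest of the others gave 0. Of the 35 splits of the CuCl2 and blank arrays, only 1, the real one with 1726 calls, gave as many, and the highest other gave 17. Some of these splits set the dyes against each other. Of the 18 that keep 2 arrays of each dye per group, the real one alone gave as many in both comparisons, with 0 and 17 as the highest other, and 18 splits are too few for a share under 0.05. For CuO against CuCl2 the real count was 0, which all 35 splits reach by construction, so the splits decide nothing there; the highest other gave 9.

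Large rises outnumbered large falls against blank in both copper groups, 46 against 6 for CuO and 84 against 5 for CuCl2 over 4-fold, on the likely reading of the table as base 2 and sample over reference; with the sign turned, these are 6 rises against 46 falls and 5 against 84. The ratio of rises to falls stayed at 7.43 or more with each blank left out (CuCl2 falls 2 to 9) and at 3.85 or more within one dye orientation (CuCl2 falls 3 on the cy3 and 30 on the cy5 arrays), which argues against a single blank array or the dyes as the whole cause. The normalization of the arrays stays open, since quantile normalization left 19 rises against 7 falls for CuO, a ratio of 2.71. For CuCl2 it left 28 against 5, a ratio of 5.6. Scaling to one median absolute deviation left, called or not, 31 against 7 for CuO, a ratio of 4.43. For CuCl2 that scaling left 50 against 3, a ratio of 16.7. Centring every array on its median left a ratio of at least 7.67, but the medians were already near 0, so this decides nothing about centring. No biological explanation was tested. A background floor that compresses falls, or the unstated choice of rows, stays open, since neither intensities nor any probes outside these rows were used here.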
